A study of Homo sapiens with 6 samples.

How the data were processed

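R-loops are structures in which an RNA strand pairs with a DNA strand and displaces its partner. They were mapped with MapR, a CUT&RUN-type assay in which RNase H fused to micrococcal nuclease (RH-MNase) releases chromatin around RNA-DNA hybrids, and GST-MNase serves as the background enzyme. The cells were IMR90, a human lung fibroblast line, grown at 2% oxygen. The series holds 6 libraries, 1 for each enzyme in proliferating, senescent and quiescent cells. Peak lists of the 3 RH-MNase libraries were used; the GST-MNase libraries are not analysed here. Senescence was induced by ectopic Ras, and the Ras construct is not given in the sources used here.

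Each deposited list gives the position of a peak and a score, a whole number of at least 10 whose scale is not stated. Per the submitters' processing notes the tools were FastQC 0.11.9, Bowtie2 2.4.5 and MACS2 2.2.7.1 and the build GRCh38. Their settings, the use of the GST-MNase library as a control and the read filters are not given in the sources used here. Each list comes from 1 library. The read depth is unknown, so the number of peaks cannot be set against it. The scores are the authors' and were used only to rank or select peaks within a list.

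Genes came from a RefSeq table of GRCh38 with 59792 entries, of which 58419 were used, among them 19821 protein-coding and 17904 lncRNA genes. Genes on alternate or unplaced sequences, the Y chromosome and the mitochondrial genome were left out. The table gives neither strand, exons nor sequence. A planned promoter window therefore became a window of 1000 bp around either annotated end of a gene, called a gene end here. Peaks were classed as at a gene end, inside a gene or outside genes, over protein-coding and lncRNA genes, in place of the planned exon and UTR classes. A locus is the gene with 1000 bp on each side. A planned look at GC content and GC skew was not made, because no genome sequence was at hand.

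Peaks overlapped when they shared at least 1 bp. Each share of peaks was set beside the median of 100 random placements of the same widths on the same chromosome, within 1 Mb bins that hold a gene or a peak, and beside 100 shifts of each peak by 20 to 100 kb. Shares carry 95% Wilson intervals and differences of shares Newcombe intervals, and both cover counting error only. With 1 library per group there are no replicates, and no p-value or standard error between conditions was computed.

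Before the data were examined, 15 gene lists were fixed. They were genes of the senescence-associated secretory phenotype (SASP), E2F targets and cell cycle genes, CDK inhibitors and p53 targets, replication-dependent histones, ribosomal proteins, fibroblast matrix and cytoskeleton, nucleic acid sensing and interferon, R-loop factors, immediate early genes and MAPK feedback, lysosome with autophagy and FOXO, common fragile site genes, small nuclear and related RNAs, loci often used as positives in DNA-RNA hybrid immunoprecipitation (DRIP), markers of other tissues, and olfactory receptors. Of 28 small RNA genes written down 25 were found, and of 20 DRIP loci the 17 protein-coding ones were used. For each list the members with a peak were counted, and the list was placed among 10000 random lists of the same size. The plan was to place the share of members in each library by itself. The difference between libraries was not part of it. Random members were matched on gene length decile and, in place of the planned promoter GC, on the quintile of protein-coding genes within 500 kb; those for the small RNA list came from non-coding small RNA genes. A percentile describes these libraries and is no test across cells.

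Genes were named by a rule set at the same time and then changed because strand is unknown. Gene ends replaced promoters, and 5000 bp on both sides replaced 5000 bp before the start and 1000 bp after the gene. For each ordered pair of libraries it takes up to 10 protein-coding genes with a gene-end peak in the first list and no peak from 5000 bp before to 5000 bp after the gene in the other, ranked by score. It also takes the 10 genes with the best lower rank in both lists, up to 4 members of each fixed list, the 3 highest peaks of each library, and a set of genes written down by name; some genes that it takes are not reported here. Other genes named here were chosen after their values were seen.

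The alternatives set at that time were peaks at or above the median score of their list (in place of a q threshold, which the lists do not give), equal numbers of peaks, an overlap of at least 50% of both peaks, peaks within 1000 bp, merged peaks, windows of 500 and 3000 bp, chromosomes 1 to 22 and X alone, lists without dense 1 Mb bins and peaks over 20000 bp, and random lists matched on length alone. The cut at the median score kept the upper part of each list by rank, with ties at that score broken in favour of wider peaks. Some peaks at the median score itself were therefore left out. After the data had been looked at, these were added: the percent of a locus covered by peaks with the ratio of its list mean, a proliferating list shortened to the covered length of the senescent list by score (equal covered length), list percentiles under other sets of peaks, the shifted placements, counts by gene type with 200 bp on each side of a gene, ribosomal DNA, 1 Mb bins with at least 60 peaks in the proliferating and senescent lists together, genes ranked by covered bases, the SASP list without its chromosome 4 cluster or with as many members dropped at random, and the neighbours of histone genes limited to those that have a peak and do not lie inside another one.

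Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 with a fixed seed. On simulated intervals the overlap and covered bases were checked against direct counting and were equal in 100% of intervals, and a planted overlap of 40% was recovered as 40%. By the mean difference in covered percent, 7% of 200 lists with no effect fell outside the central 95% of random lists. By the same measure 100% of lists stripped of their senescent peaks fell below the 2.5th percentile, which their construction makes near certain. The gene-end difference and the covered ratio were not checked in this way.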

Results

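R-loop signal was mapped in IMR90 fibroblasts that were proliferating (control vector), senescent (ectopic Ras) or quiescent (starvation), with 1 RH-MNase peak list per state. The proliferating list held 101802 peaks with a median width of 550 bp that covered 85.4 Mb. The senescent list held 85564 peaks of 468 bp over 54.1 Mb, and the quiescent list 9736 peaks of 352 bp over 4.12 Mb. Peaks wider than 2000 bp made up 8.05% of the proliferating, 2.55% of the senescent and 0.175% of the quiescent list. The median score was 22, 19 and 20, and the highest 151, 103 and 98. Read depth is unknown, and there are no replicates, so every difference below is between 2 single libraries.

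The comparison of proliferating with senescent cells asks how R-loops differ when fibroblasts enter Ras-induced senescence. Replication-dependent histone genes, which supply histones for DNA replication, had on average 71.8% of the locus under peaks in proliferating cells (SD 19.6 across 53 genes) and 11.5% in senescent cells (SD 13.7). Ribosomal protein genes went from a mean of 33.9% (SD 22.2, 80 genes) to 14.9% (SD 12.2), and genes of R-loop factors from 11.6% (SD 12.2, 30 genes) to 5.0% (SD 6.77). Genes of the senescence-associated secretory phenotype (SASP), the cytokines, proteases and growth factors that senescent cells secrete, had 25.3% (SD 21.6, 36 genes) and 21% (SD 24.5). Across all 19821 protein-coding genes the mean was 12.7% in proliferating and 8.04% in senescent cells, a ratio of 0.634.

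Of the proliferating peaks, 49.9% (95% Wilson interval 49.6 to 50.2) overlapped a senescent peak, against 4.85% under random placement and 11.1% after local shifts. Of the senescent peaks, 65.7% (65.4 to 66.1) overlapped a proliferating peak, against 5.95% and 13.7%. Where at least 50% of both peaks had to overlap, the shares were 25.5% and 30.4%. With any overlap counted, there were 51025 proliferating peaks without a senescent counterpart and 29312 senescent peaks without a proliferating one. The overlap grew with the score. In the lowest-scoring of 5 equal groups 22.1% of proliferating peaks had a senescent partner, and in the highest-scoring group 87.5%; for senescent peaks the shares were 39.9% and 89.4%.

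**Figure D1:**
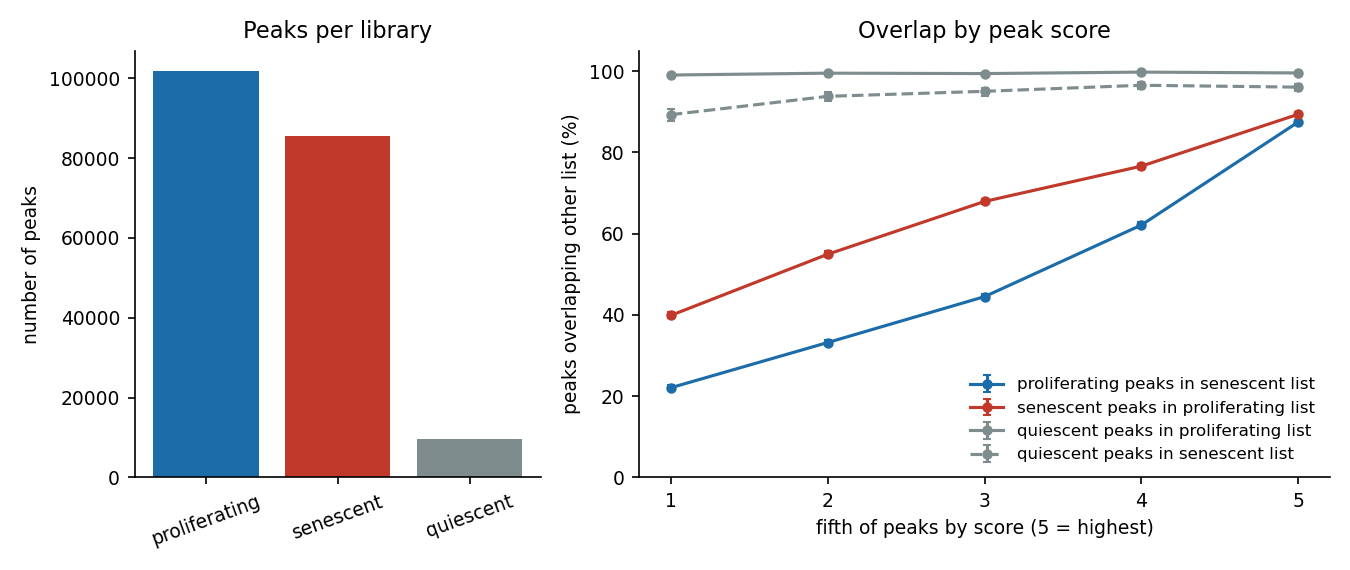
Peaks of the 3 RH-MNase libraries: the numbers per library, and the share of peaks that overlap another list (percent, with 95% Wilson intervals) in 5 groups of rising score. The share of proliferating peaks with a senescent partner runs from 22.1% to 87.5%, and that of quiescent peaks with a proliferating partner stays between 99.0% and 99.7%.

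Ends of genes carried 23.6% (23.4 to 23.9) of proliferating peaks and 26.2% (26.0 to 26.5) of senescent peaks, against 7.06% and 6.62% under random placement. Regions outside genes held 24.1% and 25.6%, against about 40.2% and 40.3% at random. Peaks with a partner in the other list lay at gene ends more often, with 33.9% against 13.4% for proliferating and 34.6% against 10.3% for senescent peaks. They were also wider, with a median of 905 against 390 bp in proliferating and 579 against 346 bp in senescent cells, and higher in score (29 against 18 and 21 against 16), and the shares were not matched on either. The gene-end share was 2.60 percentage points higher in senescent cells with all peaks, but the sign turned to -16.3 points with equal numbers of peaks and to -11.5 points at equal covered length.

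A gene-end peak was present in 15042 protein-coding genes in proliferating and 13926 in senescent cells, with 13432 in both lists. Proliferating cells alone had it in 1610 genes and senescent cells alone in 494. This split turned when the proliferating list was shortened to the covered length of the senescent list: 802 genes were then found in proliferating cells alone and 1874 in senescent cells alone, from 40460 proliferating and 85564 senescent peaks. With equal numbers of peaks the numbers were 3394 and 1286. The covered percent of the locus was higher in senescent cells for 2626 genes, lower for 14370 and equal for 2825.

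Among genes with a proliferating gene-end peak and no senescent peak within 5000 bp, 564 in all, the highest scores belonged to ATP5MK (chromosome 10, 103389050 to 103396475, score 81), which encodes a small subunit of ATP synthase, PIK3C3 (74), the lipid kinase that starts autophagosome formation, ZNF57 (71), and TMEM139, CASP2 and EIF3L (70 each). CASP2 encodes a caspase and EIF3L a subunit of a translation initiation factor. LACTB2 and XKR9, neighbours on chromosome 8, shared a peak of score 69, and ZSCAN2 (65) and ZNF486 (64) completed the 10. The reverse set held 149 genes. Its highest scores were those of CCR1, a chemokine receptor gene (chromosome 3, 46201711 to 46208313, score 30), AMBN (30), which encodes an enamel matrix protein, RSKR (29), BPIFA2 (28), SLC27A6 (26), and NGB, RNASE8, LOC105369787, OR52K1 and CYP3A5 (25 each). Genes high in both lists included PPP1R12C (126 and 89), SIRT5, a mitochondrial deacylase gene (117 and 68), NIBAN3 and COLGALT1 (117 and 61), RANBP10 and TSNAXIP1 (112 and 57), NBPF1 (100 and 60), BAK1, which encodes a pro-apoptotic protein (119 and 54), CCDC15 (99 and 54) and MYMX (98 and 61).

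All 53 histone genes had a gene-end peak in proliferating cells, 30 had one in senescent cells and 1, H1-5, in quiescent cells. The difference between senescent and proliferating cells was -43.4 percentage points (-56.7 to -29.2), below all 10000 random lists (percentile 0). Neighbouring histone genes share peaks, as H2BC21, H2AC20 and H2AC21 do in both lists. The interval and the random lists treat the 53 genes as separate, so both understate the spread. The covered percent was lower in senescent cells for 53 of 53 genes. Their covered ratio of 0.159 lay below all random lists too, which had a median of 0.631 and a central 95% of 0.502 to 0.764. H2AC16 (63.1% covered), H2AC14 (53.1%) and H2AC17 (100%) had no senescent peak, and H1-5 had 60.9% in proliferating, 20.7% in senescent and 12.3% in quiescent cells. At equal covered length 48 of the 53 had a proliferating gene-end peak and the percentile of the ratio was again 0. With the 9736 highest peaks of each list only 5 proliferating and 2 senescent members had one; the gene-end difference then lay at percentile 46.3 and the ratio at 3.01, both inside the central 95% of random lists.

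**Figure D2:**
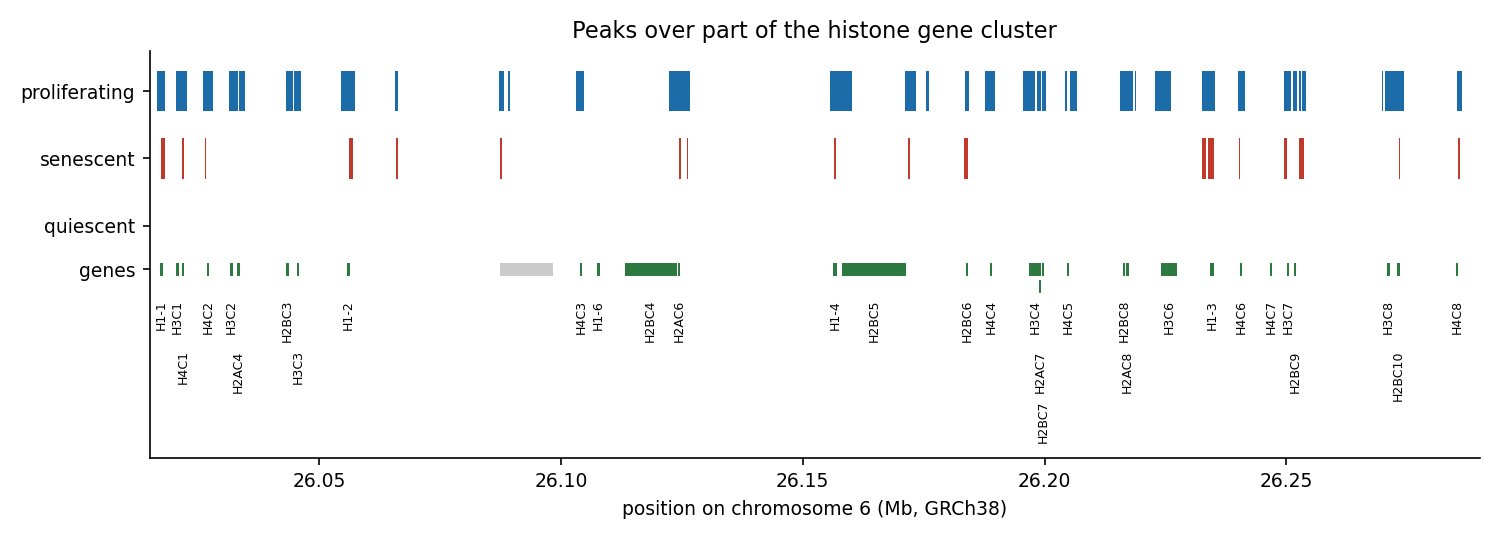
Peaks of the 3 libraries (bars) and genes over 275 kb of the histone cluster on chromosome 6, from H1-1 to H4C8 (position in Mb, GRCh38), with histone genes in green. Proliferating cells had 35 peaks over 21.1% of the segment, senescent cells 18 over 3.58% and quiescent cells 0.

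Ribosomal protein genes had a gene-end peak in 79 of 80 members in proliferating and 70 in senescent cells. Their covered ratio of 0.439 was below all random lists (0.527 to 0.719), with 76 members lower and 3 higher in senescent cells; at equal numbers of peaks it lay at percentile 1.62. RPS15A (13.2%) and RPL22L1 (12.7%) had no senescent peak, RPL13A had 44.1% and 15.3%, and RPL29 had 25.7% and 29.8%. For R-loop factors the members with a gene-end peak numbered 30 and 27, and the ratio was 0.432, at percentile 0.810 with all peaks and 2.64, inside the range, among peaks at or above the median score. The gene-end differences lay inside the range with all peaks, at percentile 8.6 for ribosomal proteins and 26.9 for R-loop factors. For ribosomal proteins the difference lay below the range at equal covered length (0.02), among peaks at or above the median score (0.06) and with equal numbers of peaks (0.405). For R-loop factors the percentiles in these settings were 3.33, 0 and 13.4. Among R-loop factors RAN, the small GTPase of nuclear transport, had 38.7% of its locus covered in proliferating cells and no senescent peak, and the helicase gene DDX21 had 4.89% and none. With equal numbers of peaks the covered ratio of the R-loop factor list lay at percentile 11.7, inside the range of random lists. The series title names 2 genes of this list. DDX1, an RNA helicase gene, had 1 peak over 2.59% of its locus in proliferating and 1 over 2.70% in senescent cells, and XPO1, the nuclear export receptor gene, had 2 peaks over 4.73% and 2 over 2.81%.

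SASP genes had a gene-end peak in 32 of 36 members in proliferating and 28 in senescent cells, a difference of -11.1 points (-28.3 to 6.56) at percentile 13.9. Their covered ratio of 0.830 stood above the random lists (median 0.618, 0.459 to 0.785; percentile 99.3), so the share of members with a peak and the covered percent ranked on opposite sides of the random median. The covered percent was higher in senescent cells for 12 members and lower for 21. CSF2, the gene of a myeloid growth factor, had 37.9% in proliferating and 70.8% in senescent cells, CSF3 77.3% and 89.5%, LIF 71.0% and 80.7%, and IL1B 2.16% and 10.5%. IL6 had 43.9% and 25.8%, IGFBP3 38.2% and 3.75%, and IL1A had no peak in any list. CXCL8 (13.2%), TNFAIP3 (13.9%) and CCL20 (14%) had no senescent peak. CXCL3 (49.8% and 58.5%) and IGFBP5 (32.8% and 29.7%) were named by rule from the members with a gene-end peak in all 3 lists. At equal covered length the SASP ratio was 0.955, at percentile 90.3 and inside the random range; among peaks at or above the median score the ratio lay at percentile 88.5 and the gene-end difference of -33.3 points at percentile 0.155.

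**Figure D3:**
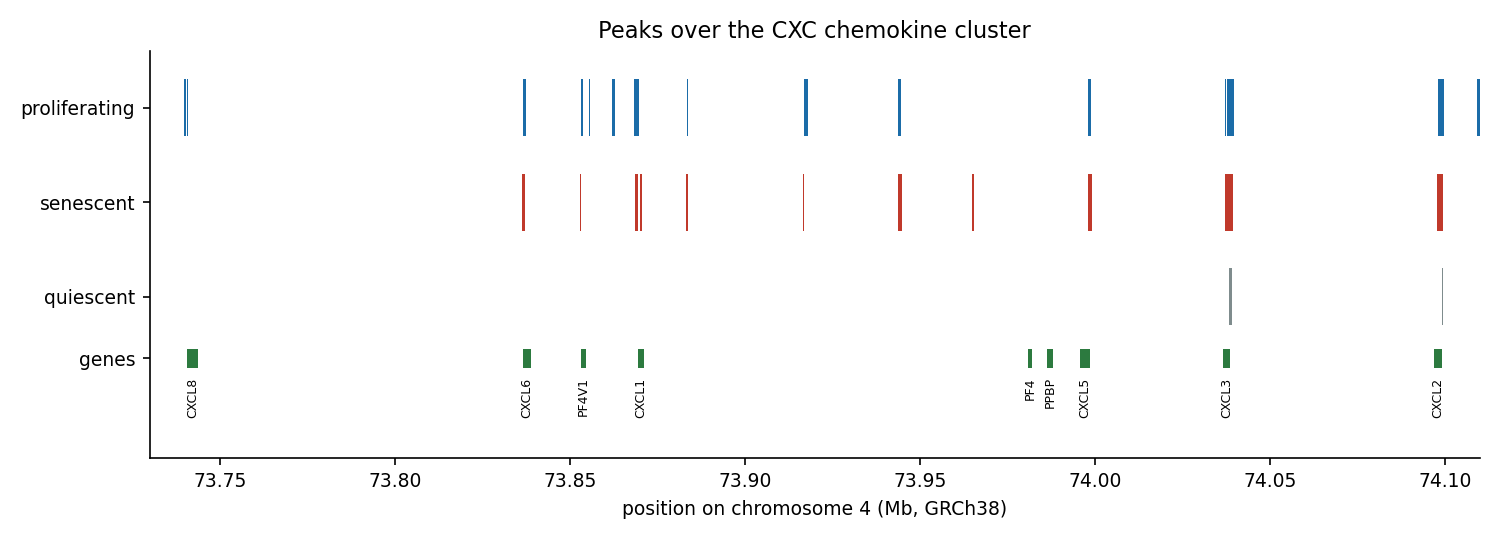
Peaks of the 3 libraries (bars) and genes over 380 kb of the chemokine cluster on chromosome 4, from CXCL8 to CXCL2 (position in Mb, GRCh38). Proliferating cells had 15 peaks over 3.12% of the segment, senescent cells 12 over 2.76% and quiescent cells 2 over 0.333%.

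E2F targets and cell cycle genes had a gene-end peak in 32 of 32 members in proliferating and 29 in senescent cells, and the covered percent was lower in senescent cells in 32 of 32. The list ratio was 0.521, at percentile 7.71. MYBL2 (4.82% in proliferating cells) had 2 senescent peaks but none at a gene end, PCNA, the DNA polymerase clamp gene, had 23.7% and 12.8%, and LMNB1, a nuclear lamina gene, 5.80% and 2.81%. CDC20 had 52.4% and 38.4% and CCNE2 18.3% and 12.7%. CDK inhibitors and p53 targets had a gene-end peak in 19 of 20 members in both states, with a ratio of 0.661 at percentile 68.9. CDKN1A, the p21 gene, had 50.8% and 25.2%, CDKN2A, the p16 gene, 40.8% and 17.5%, TP53I3 46.5% and 39.9%, and BTG2 31.6% and 34.3%.

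Immediate early and MAPK feedback genes, which answer to Ras signalling, had a gene-end peak in 32 of 33 members in both states. With equal numbers of peaks 23 proliferating and 13 senescent members had one, a difference at percentile 0.15. With all peaks the covered percent was lower in senescent cells in 33 of 33, with a ratio of 0.448 at percentile 3.74. At equal covered length the ratio lay at percentile 1.04, outside the central range, and inside at 8.19 among peaks at or above the median score and at 8.72 with equal numbers of peaks. EGR1 had 55.5% and 22.1%, EGR3 46.1% and 13.9%, and JUNB 100% and 62.6%. Fibroblast matrix and cytoskeleton genes had a gene-end peak in 30 and 27 of 33 members and a ratio of 0.513 at percentile 17.2. LUM (4.53%) and DCN (4.49%), neighbouring proteoglycan genes on chromosome 12, had no senescent peak, COL5A1 had 18.2% and 7.28%, LGALS1 67.5% and 61.3%, and ACTB 100% and 29.5%. Nucleic acid sensing and interferon genes had a gene-end peak in 25 and 22 of 31 members and a ratio of 0.663 at percentile 54.3. CGAS, a sensor of cytosolic DNA, had 4.75% and 3.0%, STING1, its adaptor, 46.3% and 27.2%, MAVS 7.76% and 6.91%, and IRF9 28.6% and 20.9%. IFI16 (4.77%) had no senescent peak, TLR3 (5.26%) had a senescent peak but none at a gene end, and ZBP1, with 6.77% of its locus covered in senescent cells, had no proliferating peak.

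Lysosome, autophagy and FOXO genes had a gene-end peak in 27 of 28 members in both states and a ratio of 0.618 at percentile 46.9. NBR1 had 10.4% and 6.72% and CCNG2 18.8% and 16.1%, MAP1LC3B (23%) had no senescent peak, and PDK4 (1.97%) had no proliferating peak. Common fragile site genes had a gene-end peak in 21 and 20 of 32 members. Their mean covered percent was 0.469% and 0.311%, a ratio of 0.663 at percentile 94.0, and 1.27 at percentile 97.7 at equal covered length. Among peaks at or above the median score the ratio was 0.608 at percentile 96.4, and with equal numbers of peaks 0.458 at percentile 45.8. FHIT had 12 proliferating and 15 senescent peaks and SDK1 8 and 6, with no senescent gene-end peak in either; MAGI2 had 20 and 17 and WWOX 6 and 4. Small nuclear and related RNA genes had a gene-end peak in 25 and 19 of 25 members, a difference of -24.0 points (-43.4 to -5.73) at percentile 2.94, and below all random lists with equal numbers of peaks (10 and 3 members), with a ratio of 0.374 at percentile 41.1. DRIP positive loci had one in 17 and 16 of 17 members and a ratio of 0.450 at percentile 4.60; CALM3 had 43.1% and 28.6%, and ING3 (4.21%) had no senescent peak. Markers of other tissues had one in 21 and 16 of 38 members and a ratio of 0.681 at percentile 63.0; SFTPC, a gene of lung alveolar cells, had 69.9% and 28.2%, and NEUROD1 (11.3%) and HBA2 (13.7%) had no senescent peak. Olfactory receptors had one in 11 of 387 members in both states, with means of 0.179% and 0.154% covered. Their ratio of 0.862 lay above all random lists. It rests on the 14 proliferating and 16 senescent members with any peak, where random lists had a proliferating median of 22.6% covered. So near the floor, its place among random lists says little about these genes. OR52K1 and OR2A42 had a senescent peak alone. The measure planned before the data were examined was the share of members with a peak in each library by itself. In proliferating cells only nucleic acid sensing (percentile 63.9) and fragile site genes (27.4) lay inside the central 95% of random lists. In senescent cells histones (64.5), fibroblast matrix (95.2), nucleic acid sensing (44.4) and fragile site genes (36.4) lay inside. All others lay above, except tissue markers and olfactory receptors, which lay below. The gene-end difference between the states was not in that plan. It lay outside for 2 of the 15 lists with all peaks, histones below and olfactory receptors above. That held for 2 lists with matching on length alone, 3 at equal covered length, 5 among peaks at or above the median score and 4 with equal numbers of peaks. Random lists were not matched on the proliferating share. Olfactory receptors, with 11 of 387 members, could lose at most 2.84 points where random lists had a median of -4.91. They could thus only lie above that median with all peaks. Histones began at 53 of 53 members, against a random median of 60.4%, and had more room to fall. The covered ratio, added after the data had been looked at, lay outside for 5 lists with all peaks, 3 below and 2 above. The number was 7 (5 below, 2 above) at equal covered length, 6 (4 and 2) with matching on length alone, 3 (2 and 1) among peaks at or above the median score and 3 of 14 (3 and 0) with equal numbers of peaks. Lists inside with all peaks and outside elsewhere include DRIP loci (percentile 1.6 at equal covered length) and, with equal numbers of peaks, E2F targets (1.7) and markers of other tissues (0.01). In that last setting tissue markers had 1 proliferating and 1 senescent member with a gene-end peak and a proliferating mean of 0.882% covered. At equal covered length their ratio lay at percentile 94.8.

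**Figure D4:**
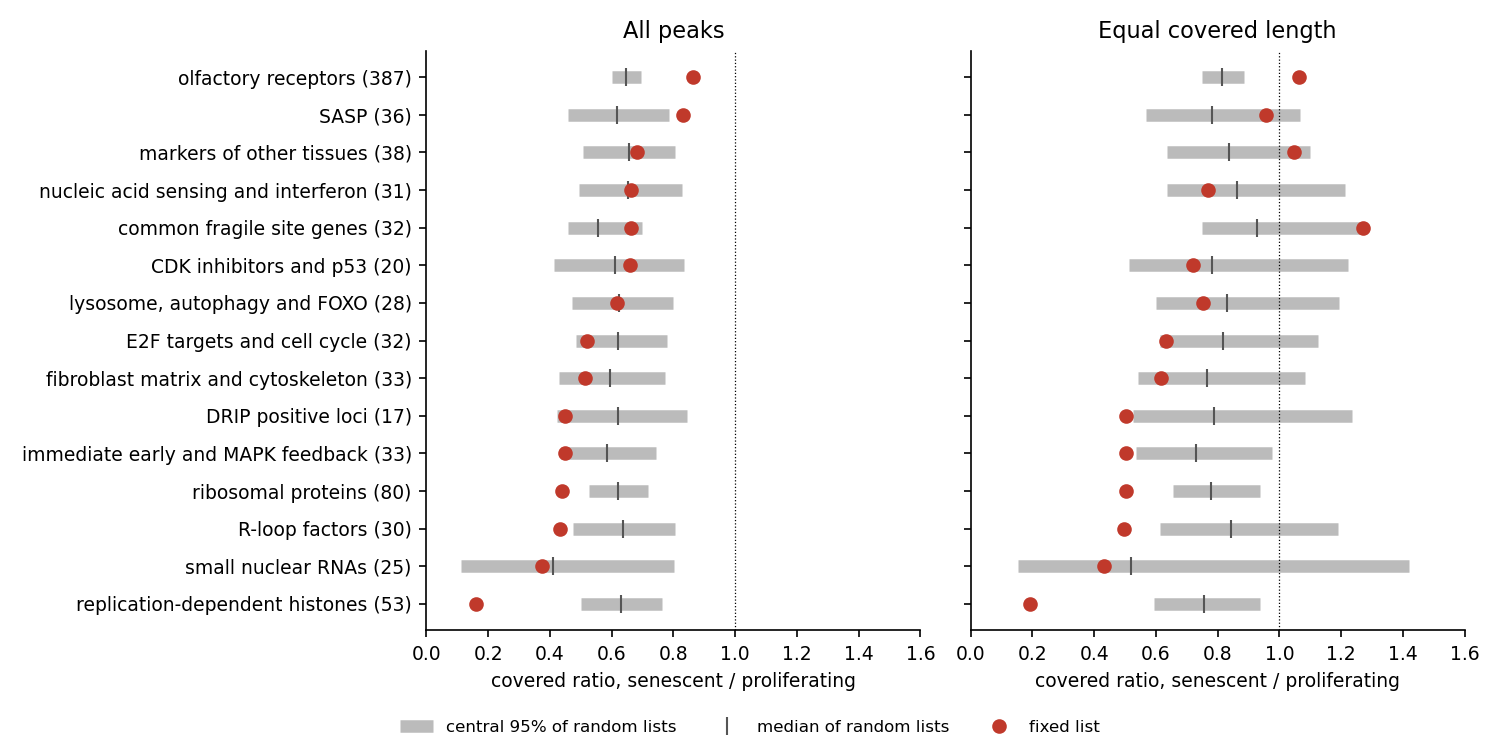
Ratio of the mean covered percent in senescent to that in proliferating cells for the 15 gene lists (points; number of genes in brackets), beside the median and central 95% of 10000 random lists (bars), with all peaks and at equal covered length. Histones lie at 0.159 and 0.193, far left of their random ranges, and SASP genes lie outside theirs with all peaks (0.830) and inside at equal covered length (0.955).

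HRAS and NRAS were looked at because the senescent cells carry an introduced Ras. HRAS (chromosome 11, 532242 to 535576) had 3 peaks over 77.5% of its locus in proliferating cells and no peak in senescent or quiescent cells. In the 50 kb on each side, outside the locus, there were 18 proliferating, 14 senescent and 1 quiescent peaks. NRAS had 2 proliferating peaks over 7.44% of its locus and none in the other states. The gene table has no exons, so signal from a cDNA could not be told from signal of the gene, and the GST-MNase libraries, in which an introduced gene would add reads too, are not analysed here.

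**Figure D5:**
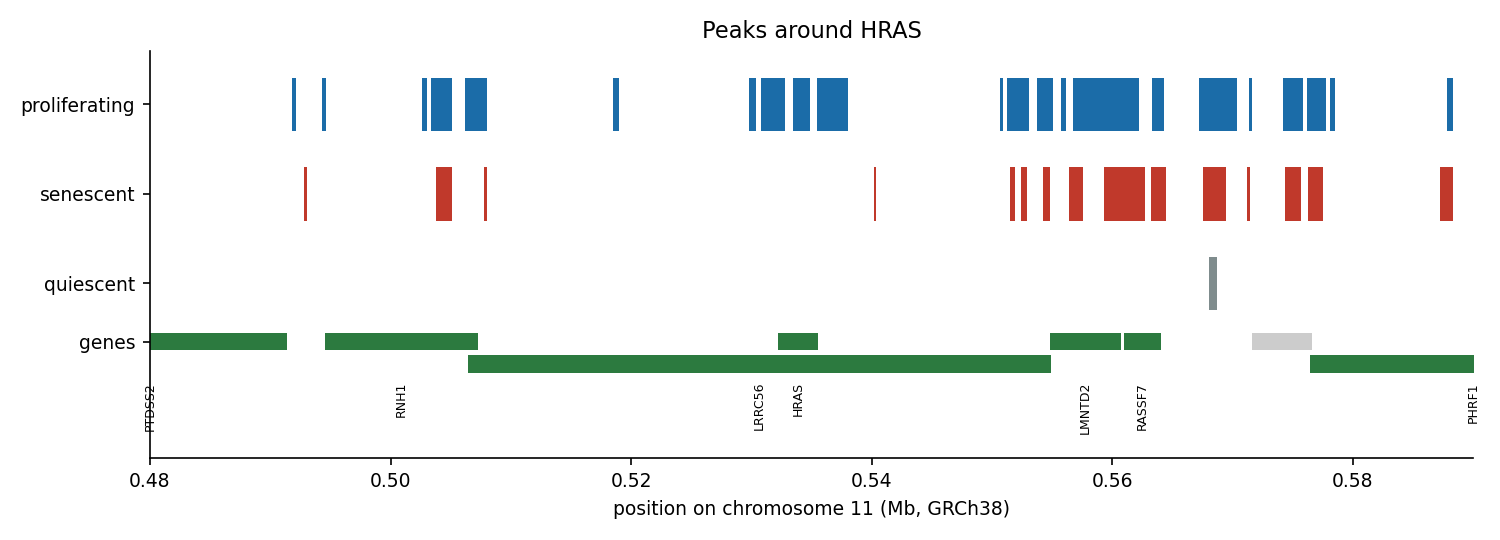
Peaks of the 3 libraries (bars) and genes in 110 kb around HRAS on chromosome 11, from PTDSS2 to PHRF1 (position in Mb, GRCh38). Proliferating cells had 22 peaks, senescent cells 15 and quiescent cells 1, and the senescent list has none over HRAS.

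The quiescent list sets a non-dividing state without Ras beside the other states. E2F targets and cell cycle genes had a gene-end peak in 5 of 32 members in quiescent cells against 32 in proliferating cells, and histones in 1 of 53 against 53. Fibroblast matrix genes had one in 20 of 33 members and immediate early genes in 20 of 33. CDKN1A, RPL13A, STING1, CGAS, IL6 and IL1B had no quiescent peak, whereas EGR1, ACTB, DDX1, XPO1 and CDKN2A had at least 1.

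Nearly all quiescent peaks overlapped a proliferating peak by at least 1 bp, 99.4% (99.3 to 99.6) against 5.44% at random and 13.4% after shifts, and 94.1% (93.6 to 94.6) overlapped a senescent peak, against 3.81% and 9.39%. Where at least 50% of both peaks had to overlap, the shares were 6.0% and 21.9%. Of the proliferating peaks 8.25% and of the senescent peaks 9.93% overlapped a quiescent one. Only 55 quiescent peaks lacked a proliferating partner and 572 a senescent partner. With the 9736 highest peaks of each list 60.3% of quiescent peaks overlapped a proliferating and 40.5% a senescent peak. Gene ends held 60.7% (59.7 to 61.7) of quiescent peaks, and regions outside genes 10.8%. The gene-end share was 37.1 points higher than in proliferating cells with all peaks and 1.79 points higher with equal numbers of peaks.

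Gene-end peaks were found in 5496 protein-coding genes in quiescent cells, of which 5431 had one in all 3 lists, 65 had none in senescent cells and 1 had none in either of the other lists. The difference of E2F targets to proliferating cells, -84.4 points where random lists had a median of -50.0, lay at percentile 0, and at 0.475 with equal numbers of peaks, with 13 proliferating and 5 quiescent members. The differences of histones (-98.1 points, percentile 0), SASP genes (-66.7, 0.475), ribosomal proteins (-63.8, 0.10), R-loop factors (-70.0, 1.34) and small RNA genes (-72.0, 0) were also below the central range. These differences also reflect proliferating shares above those of random lists. Among these lists the quiescent share by itself lay below its central range only for histones (percentile 0); it lay at percentile 6.83 for E2F targets, 54.7 for SASP genes, 54.8 for R-loop factors, 99.55 for ribosomal proteins (28 of 80 members, 35% against a random median of 22.5%) and 100 for small RNA genes (28% against 4%). With equal numbers of peaks the differences of the 5 lists other than E2F targets lay inside the central range, at percentiles 12, 61, 57.5, 41.2 and 4.15. Fibroblast matrix genes lay above it with all peaks (-30.3 points, percentile 98.9) and inside with equal numbers (65.3), and olfactory receptors, with 0 of 387 members in quiescent cells, lay at 100 and 85.8. With only 11 proliferating members their difference with all peaks could not fall below -2.84 points, where random lists had a median of -41.3. Their high place was thus fixed in advance. The other 7 lists lay inside with all peaks: CDK inhibitors and p53 at 73.3, immediate early genes at 90.4, lysosome and FOXO at 28.6, nucleic acid sensing at 15.7, fragile site genes at 19.1, DRIP loci at 9.08 and markers of other tissues at 19.6. Among peaks at or above the median score 3 of these 7 lay below it, immediate early genes at 0.43, lysosome and FOXO at 0.15 and DRIP loci at 1.975, and fibroblast matrix genes lay inside at 50.6; at equal covered length DRIP loci lay at 0.87.

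Proliferating genes without a quiescent peak nearby numbered 7768, led by OLA1 (score 127), TMEM160 (115), ABRAXAS2 (109), ZNF583 and ZNF627 (108 each), OSBPL11 (104), ACBD6 (102), and COQ6, FAM161B and TMEM68 (101 each). Senescent genes without a quiescent peak numbered 6876, led by CAPN1, a calpain protease gene, and NAPSA (72 each), FEV (71), LANCL1 and CPS1 (67), SEC14L2 (65), RPL7, RDH10 and CCDC112 (60 each) and DNASE1L2 (59). In the reverse direction, 0 genes had a quiescent gene-end peak and no proliferating peak, and 25 had no senescent one; JKAMP (36), VWA5A (32), PQBP1 (29), ZFYVE26 (25), URB1 (23), SEC62 (22), NUBP1 and LRPPRC (19 each) and ZSCAN2 (15) were among the highest of that set. Genes high in quiescent and proliferating cells included SF3A1 and CCDC157, EHD2, SLC2A4RG, MYMX, SLC29A1, KIFC1, PHF1 and PRICKLE4, and those high in quiescent and senescent cells were OGDH, MYMX, SLC29A1, GPSM3, SPINT1, FAM20C, METTL27, IMPDH1, SLC2A4RG and RANBP10. The highest single peaks lay in ribosomal DNA at RNA45SN3 (151), SLC2A4RG (146) and FAM138B (144) in proliferating cells, at SNRPCP3 (103), PPP1R12C (89) and RASA4B (82) in senescent cells, and at EPHB3 (98), PRDM11 (87) and over BRF1 and PACS2 (82) in quiescent cells.

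Along the chromosomes the number of senescent peaks for each proliferating peak ran from 0.746 on X to 0.903 on chromosome 11, around 0.840 for the whole list. Chromosome 19, which is dense in genes, had 79.6 proliferating, 64.7 senescent and 11.6 quiescent peaks per Mb, and chromosome X had 11, 8.22 and 0.884.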

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

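No test in this part was chosen after the result was seen, since the values are plain counts. Some peaks lie on unplaced sequences of the assembly, which none of the gene or region comparisons use: 162 in proliferating cells on 28 such sequences, 147 in senescent cells on 30 and 9 in quiescent cells on 5. They were looked at because they are signal outside the chromosomes, and with no control library analysed here their background is unknown.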

How the results depend on the processing

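Tests in this part chosen only after the data were seen are those at equal covered length, percentiles of the covered ratio under other sets of peaks, and all covered ratios. No paired analysis was possible because each group holds 1 library. Of the alternative values of the main results, 146 moved within counting error or, for counts, within 1.5 times, 60 moved further and 3 turned in direction; for other values the numbers were 201, 70 and 4. Results without dense bins and wide peaks, or on chromosomes 1 to 22 and X, stayed within those limits throughout. These settings removed few peaks, so the results could hardly move. The first kept 101801 of 101802 proliferating, all 85564 senescent and 9556 of 9736 quiescent peaks. The other kept 101607, 85405 and 9727. Apart from smaller lists, which follow from how the alternatives are built, the cause of the moves was not tested. Not run were a single start site per gene, GC content and skew, and a q threshold; olfactory receptors have no covered ratio with equal numbers of peaks because no member is then covered in proliferating cells. Unknown read depth limits every comparison of peak numbers.

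Cut at the median score, with ties broken in favour of wider peaks, the lists held 50901 proliferating, 42782 senescent and 4868 quiescent peaks. Of these quiescent peaks 98.7% and 88.7% overlapped proliferating and senescent ones. The gene-end share differed from proliferating cells by 0.225 points in senescent and 28.1 in quiescent cells, and 3161 genes had a gene-end peak in proliferating but not senescent cells. Senescent minus proliferating gene-end shares were -33.3 points for SASP genes, -28.1 for E2F targets, -71.7 for histones, -28.7 for ribosomal proteins, -46.7 for R-loop factors and -21.4 for lysosome, autophagy and FOXO; over whole loci they were -21.9 for E2F targets, -71.7 for histones, -25 for ribosomal proteins, -36.7 for R-loop factors and -17.9 for lysosome, autophagy and FOXO.

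With equal numbers of peaks 40.4% of proliferating peaks overlapped senescent ones, 42.8% of senescent peaks proliferating ones, and 60.3% and 40.5% of quiescent peaks proliferating and senescent ones. Gene-end shares differed by -16.3 points in senescent and 1.79 in quiescent cells, and 3394 genes had a gene-end peak in proliferating but not senescent cells and 1286 the reverse. List differences at gene ends were -25 points for E2F targets and for CDK inhibitors and p53, -5.66 for histones, -21.2 for ribosomal proteins and -30.3 for immediate early genes. Over loci they were -21.9 for E2F targets, -20 for CDK inhibitors and p53, -5.66 for histones, -18.8 for ribosomal proteins, -26.7 for R-loop factors and -21.2 for immediate early genes. HRAS and NRAS had 0 proliferating peaks, and the highest ratio of a chromosome was 1.21, above 1 by construction since the lists are equally long.

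At equal covered length the proliferating list held 40460 peaks, of which 74.8% overlapped senescent ones, and 42.3% of senescent and 96.8% of quiescent peaks overlapped proliferating ones. Gene-end shares differed by -11.5 points in senescent and 23 in quiescent cells; 802 genes had a gene-end peak in proliferating but not senescent cells and 1874 the reverse. Covered ratios were 1.27 for fragile site genes, 1.05 for markers of other tissues and 1.06 for olfactory receptors. The gene-end difference of olfactory receptors moved to percentile 0.02, from only 6 proliferating and 11 senescent members of 387.

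An overlap of 50% of both peaks gave 25.5% of proliferating peaks with a senescent partner, 30.4% the reverse, and 6.0% and 21.9% of quiescent peaks with a proliferating and a senescent partner. Within 1000 bp the values were 60.3%, 73.6%, 99.6% and 97.4%. Merged peaks gave 53.6% of proliferating and 94.6% of quiescent peaks with a senescent partner and a gene-end difference of 0.951 points between senescent and proliferating cells. A window of 500 bp gave 1.31 points for senescent and 31.3 for quiescent cells, and 3000 bp gave 35.6 for quiescent cells.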

Other observations

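Tests in this part chosen only after the result was seen are the counts by gene type, ribosomal DNA, genes by covered bases, 1 Mb bins, the tests at equal covered length, the histone test with equal numbers of peaks, the Ras flank test, the neighbours of histone genes limited to those with information, the SASP list without its chromosome 4 cluster or with members dropped at random, and the look at genes covered like HRAS without histones. Fewer tRNA, snRNA and snoRNA genes had a peak in senescent than in proliferating cells, and ribosomal DNA had less of its length under peaks. Of 429 tRNA genes, 264 had a peak within 200 bp in proliferating cells (61.5%, 56.9 to 66.0), 127 in senescent cells (29.6%, 25.5 to 34.1) and 18 in quiescent cells. At equal covered length the proliferating number was 210 against 127 in senescent cells, whereas protein-coding genes went the other way, with 14281 against 15568. Annotated snRNA genes had a peak in 57, 21 and 2 of 149, and snoRNA genes in 108, 43 and 2 of 1190. At equal covered length the proliferating numbers were 47 and 69, still above the senescent ones. The ribosomal DNA copies RNA45SN1, RNA45SN2 and RNA45SN3 on chromosome 21 were covered over 83.3%, 88.4% and 79.3% in proliferating, 41.5%, 37.3% and 46.8% in senescent and 0% in quiescent cells. These copies are nearly alike in sequence, so their peaks cannot be assigned to a copy, and how reads with several positions were handled is not given in the sources used here.

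Some long genes had more covered bases in senescent cells, ranked by the difference in bp. CELF4, an RNA-binding protein gene of neurons on chromosome 18 (37242844 to 37565798), had 13 proliferating, 53 senescent and 3 quiescent peaks, and its covered percent was 2.01%, 8.44% and 0.326%. KIF1A, a neuronal kinesin gene, had 26 and 35 peaks (9.12% and 23.4%), CDH23, a cadherin gene of hair cells, 43 and 76 (6.44% and 9.99%), RBFOX3, a neuronal splicing factor gene, 38 and 67 (3.11% and 5.52%), LINGO1 27 and 44 (5.82% and 11.9%) and CACNA2D2, a calcium channel subunit gene, 39 and 54 (14.7% and 23.4%). In the other direction stood GSE1 (25.5% and 14.8%), ZMIZ1 (49.0% and 32.7%), SEPTIN9 (46.3% and 30.0%), TRIO (13.3% and 4.32%), COL18A1 (35% and 10.9%) and SMAD3, a transducer of TGF-beta signals (37.8% and 17.8%). Of 1087 tested 1 Mb bins 181 had more senescent than proliferating peaks, around a median ratio of 0.826. The highest ratio, 3.53 (1.96 to 6.75 for counting error, the most extreme of all bins), was in the bin of CELF4 with 15 and 53 peaks; the lowest, 0.391 (0.214 to 0.688), was on chromosome 6 in the bin of SASH1 and UST with 46 and 18.

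Histone genes had a lower covered percent in senescent cells beyond what random lists had. A smaller covered length alone is argued against, since at equal covered length the list stayed below all 10000 random lists (percentile 0). Neighbouring histone genes that share peaks were counted as separate members there. That setting put 40460 proliferating against 85564 senescent peaks, so it did not match their number. With equal numbers of peaks the ratio lay at percentile 3.01 and the gene-end difference at 46.3, both inside the range. Only 5 proliferating and 2 senescent members then had a gene-end peak, so that setting cannot decide. Fewer peaks as an account thus stays open. A regional effect as large as the histone difference is argued against only where neighbouring genes had peaks. The 14 other genes within 100 kb of a histone gene had a ratio of 0.562, at percentile 16.42 of random lists (0.451 to 0.883). Only 10 of them carry information, as 3 have no peak in either state and 1 lies inside another. Their ratio was 0.578 (bootstrap over genes 0.414 to 0.757, percentile 18.9), against 0.159 for histones. On chromosome 6, which holds 50 of the 53 histone genes, it was 0.523 from only 4 genes (0.332 to 0.745). A weaker regional part thus stays open. Of these 4 genes only HFE lies among the histone genes, and its ratio of 0.263 was the lowest of the 10 (11.5% and 3.02% covered). The histone genes from H2BC11 to H2BC17 had no such neighbour with a peak, so a regional effect was not tested there. How large a regional part is inside the histone clusters therefore stays open. Exit from the cell cycle, a state shared with quiescent cells, may be the cause and stays open: with equal numbers of peaks, where few histone genes have any peak, the quiescent difference lay at percentile 11.99, neither extreme nor above the median. With all peaks, at equal covered length and among peaks at or above the median score it lay at percentile 0. There 53, 48 and 51 of the 53 members began with a proliferating gene-end peak, so they had more room to fall than random lists. Senescent and proliferating cells also differ in Ras itself, which was not tested apart.

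SASP genes had a high covered ratio with all peaks, 0.830, which means that their covered percent was less far below the proliferating one than in random lists. A senescent list of fewer and narrower peaks stays open as an account. As it predicts, the list moved inside the random range at equal covered length (percentile 90.29, ratio 0.955 against a range of 0.569 to 1.07). But that range was wider than with all peaks (0.459 to 0.785), and the ratio stayed above the random median of 0.781. The setting also put 40460 proliferating against 85564 senescent peaks, so it did not match their number. With equal numbers of peaks the ratio was 0.962 at percentile 95.9. Whether neighbouring genes of the chromosome 4 cluster, counted as separate members, account for the high ratio with all peaks stays open: without these 8 genes, whose own ratio was 1.002, the ratio of 0.783 lay at percentile 96.05, just inside a range of 0.451 to 0.803. Of 10000 draws that dropped 8 members at random 28.1% also came at or under 0.803, so the smaller list alone can do this. A biological difference at SASP genes was not tested apart from these accounts.

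HRAS had no senescent peak although 77.5% of its locus was covered in proliferating cells. Ordinary loss from a shorter senescent list stays open, since 3.526% (1.98 to 6.20, 11 of 312) of genes covered to within 10 points of HRAS also had none; 9 of the 11 were histone genes, and the other genes were PRAC1 and LOC127933115. Without histone genes the share was 0.690% (0.189 to 2.48, 2 of 290). Reads of an introduced Ras gene in the control library might remove peaks there, and 77.78% of the proliferating number of flanking peaks (14 of 18) was found in senescent cells, so the segment as a whole was not lost. The 3 lost peaks ran from 530772 to 538072 and so reached past both ends of the gene, where a cDNA adds no reads. Whether such reads can remove a peak that extends beyond them cannot be told, as the settings of the peak calls are not given. NRAS lacked senescent peaks too, and with the GST-MNase libraries not analysed here the accounts cannot be told apart.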
